A study of Mus musculus with 8 samples.

How the data were processed

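Gene expression was measured by RNA sequencing of 8 spleen samples from C57BL/6 mice aged 6 weeks. Mice were wild type or carried the R527C substitution in Lmna, and were either unirradiated (day 0) or sampled 7 days after 4 Gy, with 2 samples in each of the 4 groups. Group and replicate number were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a kit for mRNA sequencing. The growth protocol among the labels describes cultured human cells, which these samples are not, and nothing from it was used. The labels give no sex, litter, date or batch.

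The deposited file held whole-number counts of reads per gene, not normalised, with 1 column per sample, as the authors made it. Per the submitters' processing notes, Trim Galore, Subread and featureCounts were used, with the builds hg38 and mm10 named for the submission as a whole. Versions, the build used for each sample, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Reads of near-identical genes, such as immunoglobulin segments, and of overlapping or antisense genes could therefore be counted for either gene, and the counts of such genes are uncertain to that extent. The table had 52636 genes with versioned mouse Ensembl identifiers, 0 lines that named no gene, and 0 count columns that belonged to no sample. A symbol was found for 52403 identifiers by their unversioned part (49035 matched with the version too) in GENCODE M21 (GRCm38), and 233 had none. Coordinates are those of GRCm38, the assembly that mm10 stands for.

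Totals per library were 19455470 and 14738248 counts in unirradiated wild type, 19367791 and 18932468 in unirradiated mutants, 13387859 and 12100784 in irradiated wild type, and 12147309 and 16788531 in irradiated mutants. A floor of 3 counts in a library, the most that an observed count of 0 allows, corresponded to 0.154 to 0.248 CPM on the raw totals. Floors cover counting error only, since reads copied by PCR are not independent molecules. The 2 replicates of each group differed by far more than sampling noise (chi-square per degree of freedom from 21.2 to 374). This does not show that they are independent samples, and each library was counted as 1 sample by its title. Nothing in the labels says whether the 2 samples of a group came from separate mice, litters or days. The p-values measure only the spread between these samples, which may in part be technical.

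Genes were kept by filterByExpr (min.count 10, min.total.count 15), which left 17327. Counts were scaled by TMM, and CPM values use these scaled library sizes. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in 1 fit of all 8 libraries with a term for each group, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The fit had 4 residual degrees of freedom, a prior of 3.87 and a common dispersion of 0.152. The 5 contrasts were the genotype effect without irradiation, the genotype effect 7 days after irradiation, the irradiation effect in wild type, the irradiation effect in mutants, and the difference between these irradiation effects (interaction). SEs of log2 fold changes were the absolute log2 fold change divided by the square root of F. No replicate block was used, because no label says that mice with the same number belong together. The fit on all libraries uses 1 estimate of the spread for all groups, although irradiated replicates differed more than unirradiated ones.

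Fixed lists of genes (31 lists, of which 29 had at least 5 genes tested) stood for cell types, pathways, RNA quality, tissue handling and neighbouring tissue. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. List p-values were adjusted over the 29 lists within a contrast. The genes named per contrast were the 8 highest and the 8 lowest log2 fold changes among called genes whose groups did not overlap in CPM and whose mean was at least 5 CPM. Predicted and clone-named genes, immunoglobulin and T cell receptor segments and sex-linked genes were left out of this choice. To these were added Lmna, up to 4 genes with the smallest p in each list that passed or had at least 3 called genes, and up to 4 genes of the senescence, p53 and nuclear lamina lists. Groups, contrasts, lists, this rule and most alternatives were fixed before the data were examined. Genes named outside the rule were Xist and the Y-linked genes, Alb, Apoa1 and the genes said in the text to have been named after their values were seen. A list of 19 hepatocyte genes was written after Alb had been seen.

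The procedure was tested on simulated counts with the means and library sizes of these libraries, in which 200 genes were changed 2-fold, 4-fold or 8-fold. Before these changes a gene had the same mean and dispersion in every group, and genes were drawn independently. In the data irradiated replicates differed more than unirradiated ones, so the shares called are a rough guide only. With the dispersion of all 8 libraries, 0% of genes changed 2-fold were called in each of the 5 contrasts. Of those changed 8-fold, 52.8% were called in the genotype contrast without irradiation (16925 genes tested), 46.8% in that after irradiation (16972), 45.2% in the irradiation contrast of wild type (16921), 60.9% in that of mutants (16910) and 0% in the interaction (16949). Of those changed 4-fold the shares were 10.2%, 10.4%, 2.90%, 11.9% and 0% in the same order. Unchanged genes called were 0, 2, 4, 5 and 0. At that spread a count of 0 called genes in the interaction says little about changes of up to 8-fold. With the smaller dispersion of the unirradiated libraries, 53.6%, 78.0% and 91.7% of genes changed 2-fold, 4-fold and 8-fold were called in the genotype contrast without irradiation (16918 genes tested), and 23.5%, 65.6% and 77.5% in the interaction (16915). Unchanged genes called were then 18, 14, 9, 17 and 18 in the 5 contrasts.

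The alternatives were RLE scaling and no scaling, globin, immunoglobulin and T cell receptor genes left out, no low-count filter and a stricter one (at least 1 CPM in 2 libraries), DESeq2 1.42.0, limma-voom, a fit on only the groups compared, an absolute log2 fold change of at least 1, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. A library left out leaves 1 sample in its group, so the replicate difference of that group no longer enters the spread. Added after the data had been seen were limma-voom with library weights, robust empirical Bayes, genes of the X and Y chromosomes left out, and list tests in the fit on only the groups compared.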

Results

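Spleen RNA was sequenced from C57BL/6 mice aged 6 weeks that were wild type or carried the R527C substitution in Lmna, the gene for the nuclear lamina proteins lamin A and lamin C. Mice of each genotype either received no irradiation and were sampled at day 0, or were sampled 7 days after a dose of 4 Gy. The 4 groups held 2 samples each, giving 8 libraries of 12100784 to 19455470 gene counts. The deposited counts covered 52636 genes, of which 17327 passed the low-count filter and were tested. According to the study's design text, the comparison was made to learn how the mutation leads to senescence. Genes of senescence, of the p53 response and of the nuclear lamina were examined in each contrast beside markers of the spleen's cell types. Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, unless an estimated correlation is named.

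Lmna (ENSMUSG00000028063.15) lies on chromosome 3 of GRCm38, start 88480147, end 88509956. Its level was 94.9 ± 19.2 CPM in unirradiated wild-type, 86.6 ± 0.433 in unirradiated mutant, 163 ± 70.7 in irradiated wild-type and 171 ± 160.3 in irradiated mutant spleens (SD, n = 2 each). Lmna passed the test in none of the contrasts. A substitution need not change the level of its transcript, so these values do not check the genotype labels. The 2 irradiated mutant libraries had 284 and 57.7 CPM of Lmna. Replicates differed far more after irradiation: the correlation of log2 CPM between replicates was 0.982 in unirradiated wild type and 0.988 in unirradiated mutants, against 0.942 and 0.877 in the irradiated groups. Between the 2 irradiated mutant libraries, 42.7% of genes differed by over 2-fold. The first principal component (50.6% of the variance) separated irradiated from unirradiated libraries, and the second (23.0%) separated replicate 1 from replicate 2 within both irradiated groups.

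Sex-linked transcripts split the libraries by condition. All 4 unirradiated libraries had transcripts of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y (264 to 299 CPM in sum). They had at most 6 counts of Xist, the RNA that silences an X chromosome in female cells. All 4 irradiated libraries had 1029 to 1776 CPM of Xist and 0 counts of the Y-linked genes. The list sex-linked label check, made of Xist and these 4 genes, passed in both irradiation contrasts. It had adjusted p = 2.43e-21 in wild type (adjusted p = 0.0387 with an estimated correlation) and adjusted p = 1.08e-19 in mutants (adjusted p = 0.102 with an estimated correlation). The labels give no sex. Comparisons between genotypes were therefore made among libraries of like sex-linked expression, whereas irradiation, day and these sex-linked transcripts changed together. Alb, which encodes the liver protein albumin, was also absent from the unirradiated libraries (0 counts in each). The irradiated libraries had 62.9 and 70.6 CPM in wild type and 312 and 38.6 CPM in mutants.

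**Figure D1:**
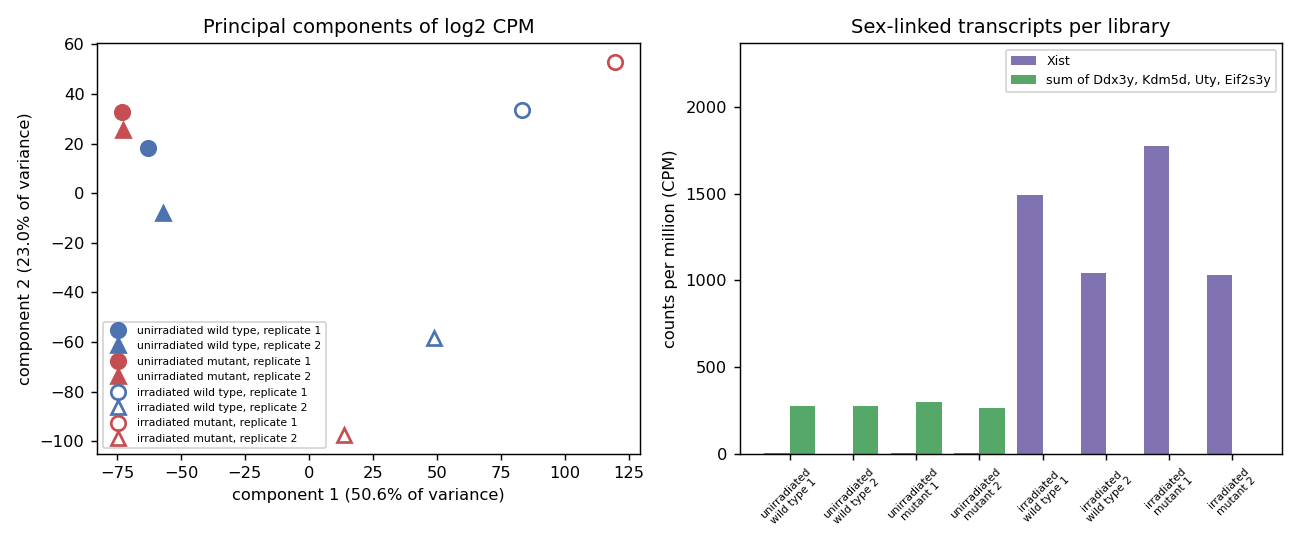
The left panel plots each library on the first 2 principal components of log2 CPM, which hold 50.6% and 23.0% of the variance. Symbols are blue for wild type, red for mutant, filled for unirradiated and open for irradiated mice. The right panel gives Xist and the sum of 4 Y-linked genes in CPM for each library. It shows 264 to 299 CPM of the Y-linked genes in the unirradiated libraries and 1029 to 1776 CPM of Xist in the irradiated ones.

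Without irradiation, transcripts of granulocytes, the neutrophil lineage, were higher in mutant than in wild-type spleens. All 20 measured genes of the granulocyte list had positive log2 fold changes, with a median of 2.40 (5.28-fold). The list rose as a set (adjusted p = 2.41e-71, or adjusted p = 0.0415 with an estimated correlation). It did not pass in the fry test (adjusted p = 0.161). Mmp9 (ENSMUSG00000017737.2, chromosome 2, start 164940780, end 164955850), a gelatinase of neutrophil granules, was at 13 ± 2.16 CPM in wild type and 75.5 ± 22.2 in mutants (log2 fold change 2.54 ± 0.37, SE). Retnlg went from 8.49 ± 0.0690 to 90.1 ± 11.3 CPM. Levels of Mmp8, the neutrophil collagenase, were 5.82 ± 1.53 and 47.9 ± 7.76 CPM, and those of Cxcr2, a chemokine receptor of mature neutrophils, 9.29 ± 0.609 and 37.1 ± 3.0 CPM (SD, n = 2 each). Adjusted over the list alone, 17 of the 20 granulocyte genes passed, while 0 passed over all genes. The first number was 8 without unirradiated wild type replicate 1, 7 without unirradiated wild type replicate 2 and 7 without unirradiated mutant replicate 2.

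Plasma cell and interferon-stimulated genes were also higher in unirradiated mutants. All 15 plasma cell genes lay above 0, with a median log2 fold change of 1.25, and the list rose (adjusted p = 1.53e-16, or adjusted p = 0.619 with an estimated correlation). Ighg1, the constant region of an IgG heavy chain, was at 64.1 ± 1.45 CPM in wild type and 1212 ± 556 in mutants. Reads shared between immunoglobulin genes can be split among them, and how such reads were counted is not given in the sources used here. Sdc1, the plasma cell surface proteoglycan CD138, was at 11.6 ± 1.15 and 31.8 ± 1.83 CPM, and Xbp1, a transcription factor of secretory cells, at 153 ± 20.5 and 333 ± 1.94 CPM. Immunoglobulin and T cell receptor genes together took 1.41 ± 0.0735% of counts in wild type and 3.01 ± 0.00610% in mutants (SD, n = 2 each). All 28 interferon-stimulated genes lay above 0 (median 0.81; adjusted p = 2.35e-14, or adjusted p = 0.543 with an estimated correlation). Among them, Ifi44 was at 14 ± 1.44 and 42.3 ± 0.0707 CPM. Oas2, a sensor of double-stranded RNA, was at 60.8 ± 8.20 and 157 ± 37.8 CPM, and Irf7, a regulator of interferon genes, at 188 ± 17.4 and 435 ± 78.8 CPM.

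Lymphocyte and stromal genes lay on the other side. The B cell list fell, with 1 of 23 genes above 0 and a median of -0.51 (adjusted p = 0.00145, or adjusted p = 0.900 with an estimated correlation). Fcmr, the IgM receptor, was at 255 ± 41.1 CPM in wild type and 112 ± 2.48 in mutants. Cd79a, a subunit of the B cell receptor, was at 872 ± 226 and 405 ± 40.7 CPM. The T cell list had 2 of 26 genes above 0 (median -0.49; adjusted p = 0.00462, or adjusted p = 0.900 with an estimated correlation). Of the stroma and matrix list, 0 of 24 genes lay above 0 (median -0.64; adjusted p = 7.20e-07, or adjusted p = 0.900 with an estimated correlation). Eln, which encodes elastin, was at 43.4 ± 2.41 and 12 ± 2.27 CPM, and Loxl1, an enzyme that crosslinks elastin, at 16.1 ± 0.196 and 6.13 ± 0.344 CPM. The granulocyte, plasma cell, interferon-stimulated, B cell, T cell and stroma lists kept their direction and the preset-correlation call whichever library was left out.

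Smaller shifts passed with the preset correlation in 5 further lists, each with adjusted p = 0.900 with an estimated correlation. The macrophage and monocyte list had a median of 0.25 (18 of 23 above 0; adjusted p = 0.0547 without unirradiated mutant replicate 1). Cd5l, a protein secreted by macrophages, was at 48.2 ± 1.12 CPM in wild type and 115 ± 16.5 in mutants. NK and cytotoxic genes had a median of 0.15 (11 of 15 above 0; adjusted p = 0.0983 without unirradiated wild type replicate 1 and adjusted p = 0.167 without unirradiated mutant replicate 1). Gzmb, which encodes granzyme B, was at 7.25 ± 0.0619 and 26.5 ± 3.12 CPM. Cell cycle genes had a median of 0.28 (31 of 33 above 0), and the immediate early and heat shock list, a sign of tissue handling, a median of -0.29 (2 of 16 above 0). Without unirradiated wild type replicate 2 the cell cycle list had adjusted p = 0.655 and the immediate early and heat shock list adjusted p = 0.354. Without unirradiated mutant replicate 1 they had adjusted p = 0.0643 and adjusted p = 0.141. Without irradiated wild type replicate 1 or 2 these cell cycle and immediate early calls were also lost (adjusted p = 0.0549 and 0.0531 for cell cycle). Cytosolic ribosomal protein genes had a median of -0.33 (0 of 24 above 0; adjusted p = 0.118 without unirradiated wild type replicate 2 and adjusted p = 0.0526 without unirradiated mutant replicate 1).

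Gene by gene, edgeR's quasi-likelihood test on all 8 libraries called 0 of 17327 genes between unirradiated genotypes (smallest adjusted p = 0.422). At an unadjusted p under 0.05 there were 388, of which 312 were higher in mutants, fewer than the 866 that chance alone would give. DESeq2 called 55 genes, limma-voom 0, and limma-voom with library weights 395. The fit on the unirradiated libraries alone, whose spread does not include that of the irradiated replicates, called 469 genes, 378 higher and 91 lower in mutants. These included all 20 granulocyte, 17 interferon-stimulated, 10 plasma cell and 4 macrophage and monocyte genes as higher and 9 B cell and 6 stroma and matrix genes as lower. In that fit Slfn4, a gene of myeloid cells that responds to interferon, rose from 25.6 ± 1.62 to 442 ± 175 CPM (log2 fold change 4.11 ± 0.27, SE). Ifitm6 rose from 22.5 ± 1.40 to 191 ± 78.2 CPM and Lilr4b, a receptor of myeloid cells, from 11.1 ± 2.72 to 79.6 ± 4.07 CPM. S100a8, a subunit of the neutrophil protein calprotectin, had a log2 fold change of 2.67 ± 0.29. Trib3, a gene of the stress response (log2 fold change -2.80 ± 0.36), Mfap4, a microfibril protein (-2.15 ± 0.23), Gpc3, a glypican (-2.14 ± 0.38), and Eln (-1.83 ± 0.19) fell. The granulocyte list's p with an estimated correlation rested on the set of libraries. It was 0.438 in the fit on the unirradiated libraries alone. With 1 library left out it was under 0.05 without unirradiated mutant replicate 1 (0.00737) or 2 (0.0315). It was between 0.115 (without irradiated wild type replicate 1) and 0.241 (without unirradiated wild type replicate 1) for each of the other 6. All 20 granulocyte genes were above 0 each time. Leaving out irradiated mutant replicate 1 or 2 gave 15 and 14 called genes.

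**Figure D2:**
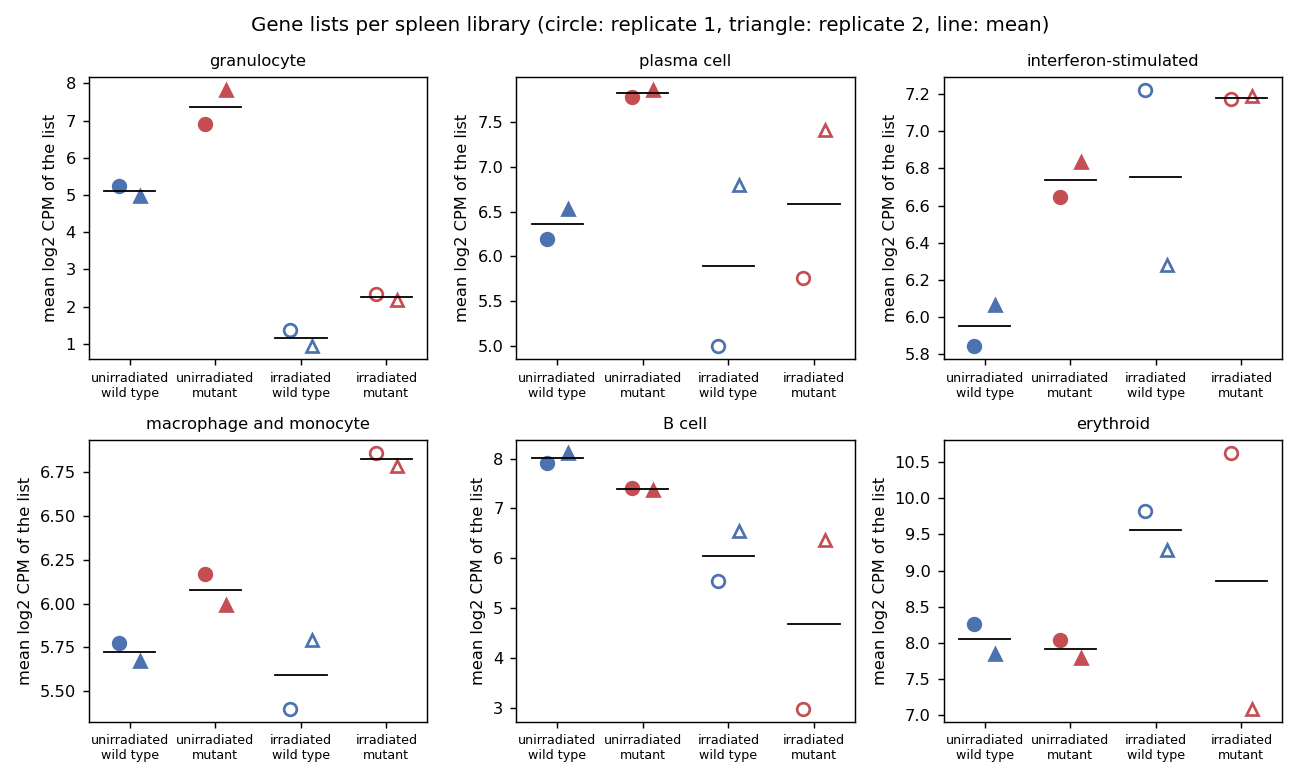
Each panel plots the mean log2 CPM over the genes of 1 list in each library. Symbols are circles for replicate 1, triangles for replicate 2, blue for wild type, red for mutant and open for irradiated mice, and lines mark means. Granulocyte means were 5.11 ± 0.18 in unirradiated wild type and 7.38 ± 0.65 in unirradiated mutants. Those of macrophage and monocyte genes were 5.59 ± 0.28 in irradiated wild type and 6.82 ± 0.05 in irradiated mutants (SD, n = 2 each).

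Among mice sampled 7 days after irradiation, macrophage transcripts were higher in mutant spleens. All 23 genes of the macrophage and monocyte list had positive log2 fold changes, with a median of 1.13. The list rose (adjusted p = 8.70e-25, or adjusted p = 0.187 with an estimated correlation). It did not pass in the fry test (adjusted p = 0.0848). C1qc, a chain of complement C1q made by tissue macrophages, was at 203 ± 32.4 CPM in irradiated wild type and 518 ± 28.9 in irradiated mutants (log2 fold change 1.35 ± 0.30, SE). The gene is ENSMUSG00000036896.5, chromosome 4, start 136889804, end 136893065. Cd5l, a protein secreted by macrophages, was at 42.1 ± 3.76 and 176 ± 105 CPM, and Slc11a1, a metal transporter of phagosomes, at 22.3 ± 4.47 and 49.5 ± 7.29 CPM. Vsig4, a complement receptor of resident macrophages, was at 0.0901 ± 0.127 and 5.30 ± 4.02 CPM (SD, n = 2 each). Adjusted over the list alone, 15 of the 23 genes passed, and 0 passed over all genes. The first count was 2 without unirradiated wild type replicate 1 or 2, 0 without unirradiated mutant replicate 1 or 2 or irradiated wild type replicate 1, and 8 without irradiated wild type replicate 2. The macrophage and monocyte list kept its direction and preset-correlation call whichever library was left out, with medians from 0.96 to 1.40, and 19 of its 23 genes lay above 0 without irradiated mutant replicate 2. The 2 mutant libraries had list means of 6.86 and 6.79 log2 CPM, against 5.40 and 5.79 in wild type.

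Granulocyte genes also lay higher in irradiated mutants, with 16 of 20 above 0 and a median of 0.70 (adjusted p = 3.30e-08, or adjusted p = 0.775 with an estimated correlation). With 1 library left out this median ran from 0.28 to 1.33. Mpo, the myeloperoxidase of granulocyte precursors, was at 0.398 ± 0.436 CPM in wild type and 4.31 ± 0.641 in mutants. Lcn2, an iron-binding granule protein, was at 3.99 ± 3.15 and 47.3 ± 57 CPM, and its mutant mean rested mostly on 1 library. The granulocyte list lay low in both irradiated groups, with means of 1.16 log2 CPM in wild type and 2.26 in mutants. The wild-type level of Mpo was near the floor of 3 counts (0.268 CPM), so the size of its difference is uncertain. Adjusted over the list alone, 3 granulocyte genes passed (0 without unirradiated wild type replicate 1 or 2, 1 without irradiated wild type replicate 1 and 5 without irradiated mutant replicate 1). Of the 17 lists past the preset threshold, the granulocyte and the macrophage and monocyte lists were the 2 that kept their call and direction whichever library was left out. Their estimated correlations were 0.252 and 0.185, against the preset 0.01.

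The other 15 lists lost the call or turned when at least 1 irradiated library was left out. NK and cytotoxic genes had a median of 0.56 (adjusted p = 3.38e-04, or adjusted p = 0.845 with an estimated correlation). The median was -0.25 without irradiated mutant replicate 2 (adjusted p = 0.448), and the call was also lost without irradiated wild type replicate 1 (adjusted p = 0.202). Gzma, which encodes granzyme A, was at 17.8 ± 0.00604 CPM in wild type and 43.3 ± 7.29 in mutants. B cell genes had a median of -0.62 (adjusted p = 8.87e-07, or adjusted p = 0.845 with an estimated correlation). The median was 0.30 without irradiated mutant replicate 1 (adjusted p = 0.150), and the call was also lost without irradiated wild type replicate 2 (adjusted p = 0.114). The B cell list means were 2.98 and 6.37 log2 CPM in mutants and 5.54 and 6.55 in wild type. Interferon-stimulated genes had a median of 0.41 (adjusted p = 7.79e-04, or adjusted p = 0.845 with an estimated correlation). The interferon-stimulated list had adjusted p = 0.739 without irradiated wild type replicate 2 and 0.0529 without irradiated mutant replicate 2. Ifi44 was at 25.6 ± 18.5 and 91.7 ± 28.7 CPM. The adipose list, fixed as a sign of neighbouring tissue, had all 9 genes above 0 (median 3.09; adjusted p = 2.09e-06, or adjusted p = 0.845 with an estimated correlation). It had adjusted p = 0.359 without irradiated mutant replicate 2 and 0.0697 without irradiated wild type replicate 1. Its means were 2.24 and 5.97 log2 CPM in mutants and -0.76 and 2.94 in wild type.

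Further lists past the preset threshold at day 7, each with adjusted p = 0.845 with an estimated correlation, lost the call or turned when 1 irradiated library was left out. Plasma cell genes (median 0.49), stroma and matrix genes (0.64) and DNA repair genes (-0.19) had adjusted p = 0.359, 0.179 and 0.359 without irradiated mutant replicate 2. Without irradiated wild type replicate 1 they had adjusted p = 0.570, 0.737 and 0.189. Dendritic cell genes (-0.32) had adjusted p = 0.864 without irradiated mutant replicate 1 and 0.978 without irradiated wild type replicate 2. The immediate early and heat shock genes (-0.41) had adjusted p = 0.388 without irradiated mutant replicate 1. Cytosolic ribosomal protein genes (-0.20) had adjusted p = 0.744 without irradiated wild type replicate 1 and 0.0707 and 0.213 without irradiated mutant replicate 1 and 2. Nuclear-encoded oxidative phosphorylation genes (-0.20) lost the call in 6 of the 8 fits, those without any 1 of the 4 unirradiated libraries among them, with adjusted p = 0.971 without irradiated mutant replicate 2. The list oxidative phosphorylation (nuclear) also lost it in the fit on the irradiated libraries alone (adjusted p = 0.0554). The cell cycle list (median -0.11) turned to higher in mutants without irradiated mutant replicate 2 (adjusted p = 4.72e-06), as did the erythroid list (adjusted p = 4.16e-14). The T cell list (median -0.05) turned to higher without irradiated mutant replicate 1 (adjusted p = 5.04e-07). Without irradiated wild type replicate 1 the cell cycle and erythroid lists had adjusted p = 0.299 and 0.694. Without irradiated wild type replicate 2 the T cell list had adjusted p = 0.739. The erythroid list's median (0.08) and mean (0.16) lay above 0 while its test pointed to lower expression in mutants.

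edgeR called 0 genes between irradiated genotypes (smallest adjusted p = 0.812). At an unadjusted p under 0.05 there were 696, of which 583 were higher in mutants, again fewer than the 866 that chance alone would give. DESeq2 called 61 genes, and limma-voom 0 with and without library weights. The fit on the irradiated libraries alone also called 0 genes, with 152 at an unadjusted p under 0.05. More genes were called without irradiated mutant replicate 1 or 2. Those fits leave the difference between these 2 replicates out of the spread, so their calls say little.

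In wild type, spleens sampled 7 days after 4 Gy had far fewer granulocyte and megakaryocyte transcripts than unirradiated spleens. The granulocyte list had a median log2 fold change of -4.06 (adjusted p = 3.09e-31, or adjusted p = 0.122 with an estimated correlation). Adjusted over the list alone, 18 of its 20 genes fell. Mpo was at 50.5 ± 4.38 CPM in unirradiated and 0.398 ± 0.436 in irradiated spleens. Prtn3, a protease of primary granules, was at 48.5 ± 1.60 and 0.488 ± 0.435 CPM (SD, n = 2 each). Fcnb, a ficolin of granulocyte precursors, had 12.9 ± 1.90 CPM without irradiation and 0 counts in both irradiated libraries, at least 48-fold lower against a floor of 3 counts per library. The megakaryocyte and platelet list had a median of -2.55 (adjusted p = 2.06e-22, or adjusted p = 0.144 with an estimated correlation), and 16 of 19 genes fell when adjusted over the list alone. In this list Ppbp, a platelet chemokine, was at 204 ± 4.44 and 25 ± 0.143 CPM. Rab27b, which acts in platelet granule release, fell from 13.4 ± 0.245 to 0.759 ± 0.0741 CPM (log2 fold change -4.13 ± 0.44, SE; adjusted p = 0.0327). With Fcnb set at its bound the granulocyte median stayed at -4.06. Both lists kept their preset-correlation call whichever library was left out, and with an estimated correlation the granulocyte list had adjusted p = 0.0472 and 0.0462 without unirradiated mutant replicate 1 and 2. The call of Rab27b held without irradiated mutant replicate 1 or 2 and was lost without any of the other 6 libraries, which left 0 called genes of the megakaryocyte and platelet list.

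B cell genes were lower in irradiated wild type, with 0 of 23 above 0 and a median of -1.97 (adjusted p = 9.79e-09, or adjusted p = 0.919 with an estimated correlation). Cd22, a B cell inhibitory receptor, was at 375 ± 3.33 and 58.8 ± 23.8 CPM. The antigen presentation list had a median of -0.57 (adjusted p = 0.0339, or adjusted p = 0.921 with an estimated correlation). It had adjusted p = 0.110 without unirradiated wild type replicate 2, 0.263 without irradiated wild type replicate 1, and 0.0563 without scaling factors. The erythroid list rose as a set (25 of 26 above 0, median 1.67; adjusted p = 8.91e-06, or adjusted p = 0.921 with an estimated correlation). The cell cycle list rose in the same way (32 of 33 above 0, median 1.31; adjusted p = 1.87e-05, or adjusted p = 0.921 with an estimated correlation). The interferon-stimulated list also rose (25 of 28 above 0, median 0.84; adjusted p = 3.97e-04, or adjusted p = 0.919 with an estimated correlation), and Isg15 was at 255 ± 47.8 and 1255 ± 452 CPM. In each of these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone. Without irradiated wild type replicate 1 the cell cycle and interferon-stimulated lists had adjusted p = 0.152 and 0.424. The p53 targets had a median of 0.51 (adjusted p = 0.0453, or adjusted p = 0.412 with an estimated correlation), a call lost in 5 of the 8 fits that left out 1 library. The list had adjusted p = 0.102 and 0.0554 without unirradiated wild type replicate 1 and 2. It was 0.0960 without irradiated wild type replicate 2 and 0.0561 and 0.0567 without irradiated mutant replicate 1 and 2. The p53 targets had adjusted p = 0.0563 without scaling factors and 0.0728 in the fit on the wild-type libraries alone. In the fry test, which asks only whether the members of a list move one way, the p53 targets rose (adjusted p = 0.0134). Cdkn1a, which encodes the cell cycle inhibitor p21, was at 7.93 ± 0.588 and 49.4 ± 0.294 CPM, and Gdf15, a stress cytokine, at 1.35 ± 0.207 and 8.18 ± 1.82 CPM. Transcripts of the mitochondrial genome, a sign of RNA quality, were above 0 for all 15 genes (median 1.07; adjusted p = 6.17e-07, or adjusted p = 0.496 with an estimated correlation). The immediate early and heat shock list had a median of 0.39 (adjusted p = 0.0281, or adjusted p = 0.921 with an estimated correlation). It had adjusted p = 0.149 without unirradiated wild type replicate 1, 0.0760 without irradiated wild type replicate 1 and 0.0526 and 0.0567 without irradiated mutant replicate 1 and 2. In the fit on the wild-type libraries alone its adjusted p was 0.0676.

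edgeR called 10 genes in this contrast, 2 higher and 8 lower in irradiated spleens. Of these, 5 were Xist, Ddx3y, Kdm5d, Uty and Eif2s3y. The other 5 were Ms4a3, a gene of granulocyte precursors (9.91 ± 0.414 CPM against 0.0451 ± 0.0637; log2 fold change -7.57 ± 0.86, SE; adjusted p = 0.0416), Rab27b and 3 genes named after their values were seen. These 3 were the immunoglobulin segments Igkj5 (log2 fold change -6.73) and Igkv8-19 (-3.41) and the predicted gene Gm37529 (5.26). The irradiated level of Ms4a3 lay below the floor of 3 counts (0.268 CPM), so the size of its fall is uncertain. With genes of the X and Y chromosomes left out before the fit, 0 genes were called (smallest adjusted p = 0.0551), with 2914 at an unadjusted p under 0.05. The fit on the wild-type libraries alone called 1107 (576 higher, 531 lower), DESeq2 917 and limma-voom 5. The median of all genes moved from 0.09 to -0.25 without scaling factors. Leaving out irradiated mutant replicate 1 or 2 gave 2436 and 2551 genes, leaving out any wild-type library gave 0, and leaving out unirradiated mutant replicate 1 or 2 gave 3 and 6.

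In mutants, irradiated spleens again had far fewer granulocyte and megakaryocyte transcripts than unirradiated ones, and more transcripts of p53 targets. All 20 granulocyte genes were lower, with a median log2 fold change of -5.27 (adjusted p = 6.34e-47, or adjusted p = 0.102 with an estimated correlation), and 13 of them fell by the test over all genes. With Fcnb set at its bound this median stayed at -5.27. Ngp, the neutrophilic granule protein, fell from 1513 ± 784 to 3.47 ± 1.86 CPM. Ltf, which encodes the granule protein lactoferrin, fell from 936 ± 497 to 5.17 ± 4.42 CPM, and Camp, an antimicrobial peptide precursor, from 609 ± 354 to 6.39 ± 5.83 CPM. Cebpe, a transcription factor of granulocyte maturation, fell from 34.3 ± 21 to 0.228 ± 0.00859 CPM (SD, n = 2 each). Cd177, a neutrophil surface protein (log2 fold change -7.14 ± 0.63, SE), Ms4a3 (-6.30 ± 0.63) and Ctsg, which encodes cathepsin G (-6.15 ± 0.78), fell as well. Fcnb had 27.2 and 57.8 CPM in the unirradiated and 0 counts in both irradiated mutant libraries. In the megakaryocyte and platelet list (median -2.26; adjusted p = 1.41e-20, or adjusted p = 0.191 with an estimated correlation), 6 of 19 genes fell. They included Gp1ba, a chain of the platelet receptor for von Willebrand factor (12.8 ± 3.64 to 0.486 ± 0.139 CPM), and Tubb1, the tubulin of platelets (30.6 ± 6.01 to 1.24 ± 0.891 CPM). Without unirradiated wild type replicate 1 or 2 or unirradiated mutant replicate 2, 0 granulocyte genes fell over all genes, and 4 did so without unirradiated mutant replicate 1. The number was 12 without irradiated wild type replicate 1 or 2, and 19 and 20 without irradiated mutant replicate 1 and 2. In the megakaryocyte and platelet list it was 0 without any 1 of the 4 unirradiated libraries, 3 without irradiated wild type replicate 1 or 2, and 15 without irradiated mutant replicate 1 or 2. Adjusted over the list alone, 20 granulocyte and 14 megakaryocyte and platelet genes fell.

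The p53 target list rose (20 of 25 above 0, median 0.79; adjusted p = 0.00187, or adjusted p = 0.174 with an estimated correlation), and 3 of its genes rose by the test over all genes. Cdkn1a rose from 8.56 ± 3.10 to 110.1 ± 67.3 CPM (log2 fold change 3.68 ± 0.50, SE; adjusted p = 0.0317). The gene is ENSMUSG00000023067.13, chromosome 17, start 29090976, end 29100727. Phlda3, an inhibitor of Akt signalling, rose from 5.32 ± 0.116 to 31.4 ± 4.72 CPM (adjusted p = 0.0317). Eda2r, a receptor of the TNF receptor family, rose from 0.422 ± 0.267 to 12.1 ± 7.93 CPM (adjusted p = 0.0370). Without scaling factors the median of all genes moved from 0.15 to -0.25, and 16 of the 25 p53 targets lay above 0 (median 0.30). Adjusted over the list alone, 9 p53 targets rose and 2 fell. The number of p53 targets that rose over all genes was 0 without any 1 of the 4 unirradiated libraries, 1 without irradiated wild type replicate 1 or 2, and 7 and 8 without irradiated mutant replicate 1 and 2. The p53 targets list itself kept its preset-correlation call in all 8 fits, and rose in the fry test (adjusted p = 0.00375).

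C1qc rose from 124 ± 7.24 to 518 ± 28.9 CPM (adjusted p = 0.0370). The macrophage and monocyte list had 20 of 23 genes above 0 (median 0.96; adjusted p = 0.00188, or adjusted p = 0.750 with an estimated correlation). Its median ran from 0.43 to 1.13 with 1 library left out. The call of C1qc held without irradiated mutant replicate 1 or 2 and was lost without any of the other 6 libraries and without scaling factors (adjusted p = 0.111). All 24 stroma and matrix genes were above 0 (median 2.02; adjusted p = 5.38e-08, or adjusted p = 0.815 with an estimated correlation), with Col1a2, a chain of type I collagen, at 61.8 ± 8.33 and 277 ± 204 CPM. All 9 adipose genes were above 0 (median 4.26; adjusted p = 0.00375, or adjusted p = 0.920 with an estimated correlation). Without irradiated mutant replicate 2 the stroma and matrix list had adjusted p = 0.0725 and the adipose list 0.273. B cell genes had a median of -2.04, with 0 of 23 above 0 (adjusted p = 1.90e-10, or adjusted p = 0.750 with an estimated correlation). The B cell median ran from -4.55 to -1.26 with 1 library left out.

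Other lists past the preset threshold in this contrast, beside the sex-linked and the senescence and secretory lists, were erythroid (26 of 26 above 0, median 1.78), plasma cell (0 of 15, -0.72), endothelial (15 of 16, 0.91) and mitochondrial transcripts (15 of 15, 0.95). The first 3 had adjusted p = 0.920 with an estimated correlation and the last adjusted p = 0.750 with an estimated correlation. The erythroid means were 10.63 and 7.08 log2 CPM in the 2 irradiated mutant libraries. Without irradiated mutant replicate 1 the erythroid list turned to lower in irradiated mutants (median -0.87; adjusted p = 3.90e-06). The plasma cell list had adjusted p = 0.246 without irradiated mutant replicate 1, and the endothelial and mitochondrial lists adjusted p = 0.139 and 0.0801 without irradiated mutant replicate 2. Other genes that rose included Ccl24, a chemokine that attracts eosinophils, from 0.878 ± 0.00834 to 22.6 ± 5.92 CPM, and Nfib, a transcription factor, from 10.1 ± 0.778 to 89.4 ± 47.5 CPM. Of the 25 autosomal genes named for this contrast because they passed, 13 kept the call without irradiated wild type replicate 1 or 2, and all 25 did without irradiated mutant replicate 1 or 2. Without unirradiated mutant replicate 1 and 2, 5 and 1 kept it, and without unirradiated wild type replicate 1 and 2, 0 and 1. Fits without 1 irradiated mutant library leave the difference between those 2 replicates out of the spread, so a call kept in them says little. Alb was at 312 and 38.6 CPM in the 2 irradiated mutant libraries and at 0 counts in the unirradiated ones (adjusted p = 0.0439). The RNA component of RNase P, Rpph1 (log2 fold change 6.38 ± 0.79, SE), the 7SK RNA Rn7sk (3.96 ± 0.54), the ribosomal sequence CT010467.1 (5.02 ± 0.81) and Lars2, a mitochondrial tRNA synthetase (3.90 ± 0.56), rose with it. Rpph1 and Rn7sk are RNAs without a poly(A) tail. Counts assigned to Lars2 and to CT010467.1 were both highest in irradiated mutant replicate 1 (1708 and 29151 CPM).

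edgeR called 104 genes between irradiated and unirradiated mutants, 44 higher and 60 lower, of which 98 were autosomal. Without scaling factors 60 were called (15 higher, 45 lower), and with globin, immunoglobulin and T cell receptor genes left out 70 (37 higher, 33 lower). With genes of the X and Y chromosomes left out 96 were called, all of them among the 104. DESeq2 called 1710 genes (975 higher, 735 lower), limma-voom 105 (43 higher, 62 lower) and limma-voom with library weights 120 (102 higher, 18 lower). The balance of directions thus turned with the setting, also within edgeR when globin, immunoglobulin and T cell receptor genes were left out. The fit with edgeR on the mutant libraries alone called 0, with 2669 at an unadjusted p under 0.05. Leaving out irradiated mutant replicate 1 or 2 gave 1290 and 4428 genes, and leaving out irradiated wild type replicate 1 or 2 gave 55 and 54. Leaving out unirradiated wild type replicate 1 or 2 gave 4 and 6, and unirradiated mutant replicate 1 or 2 gave 12 and 3. All 10 genes called in wild type, 5 of them autosomal, were called in the same direction in mutants. Across genes, which are not independent replicates, the log2 fold changes of the 2 irradiation contrasts had a Pearson correlation of 0.765, and 82.2% of genes had the same sign. These contrasts had no library in common, but both set Xist-expressing against Y-expressing libraries.

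The irradiation effects of the 2 genotypes were compared with an interaction contrast, in which edgeR called 0 genes (277 at an unadjusted p under 0.05, 189 of them positive, against 866 by chance alone; DESeq2 called 2 and limma-voom 0). The granulocyte decrease was larger in mutants as a list (6 of 20 genes above 0, median -1.36; adjusted p = 4.01e-11, or adjusted p = 0.528 with an estimated correlation). The 6 genes went the other way, among them Mpo, with log2 fold changes of -6.95 in wild type and -5.95 in mutants. Mmp9 went from 13 ± 2.16 to 4.11 ± 1.32 CPM in wild type and from 75.5 ± 22.2 to 5.15 ± 1.01 CPM in mutants, starting from the higher level of unirradiated mutants. The macrophage and monocyte list moved up in mutants relative to wild type (median 0.84; adjusted p = 7.00e-10, or adjusted p = 0.528 with an estimated correlation). C1qb was at 139 ± 3.03 and 145 ± 37.8 CPM in wild type and 130.4 ± 13.1 and 341 ± 2.91 CPM in mutants. These 2 lists kept their preset-correlation call and direction in all 8 fits that left out 1 library. The p53 target list had an interaction median of 0.27 (adjusted p = 0.0463, or adjusted p = 0.554 with an estimated correlation), a call lost in 7 of the 8 fits that left out 1 library (adjusted p = 0.312 without irradiated mutant replicate 1). Between genotypes the p53 targets did not pass, with 13 of 25 above 0 without irradiation (adjusted p = 0.292) and 16 of 25 after it (median 0.17; adjusted p = 0.159). Each of the 2 genotype contrasts called 0 genes, so they could share none. Their log2 fold changes had a Pearson correlation of 0.202 across genes. In both genotypes the unirradiated libraries carried Y-linked transcripts and the irradiated ones Xist. The interaction, and any difference between the 2 genotype contrasts, therefore cannot separate irradiation from sex or day.

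Senescence genes moved in both directions between irradiated and unirradiated mutants. Between genotypes 0 of them were called over all genes. That says little, since 0% of simulated 2-fold changes were called in either genotype contrast at the spread of all 8 libraries. Of 28 measured senescence and secretory genes, 13 lay above 0 between unirradiated genotypes (median -0.10, mean 0.12, which differ in sign; adjusted p = 0.292). Without unirradiated wild type replicate 2 the list's adjusted p was 0.0257. Mmp9, which the granulocyte list also holds, was the 1 gene that passed when adjusted over the list alone, and 0 passed without unirradiated wild type replicate 1 or 2 or unirradiated mutant replicate 2. After irradiation, 21 of 28 lay above 0 between genotypes (median 0.53; adjusted p = 0.0175, or adjusted p = 0.845 with an estimated correlation). Without irradiated mutant replicate 2, 9 of the senescence and secretory genes did, with a median of -0.41 and an adjusted p of 0.448. Without irradiated wild type replicate 1 or 2 the list's adjusted p was 0.202 and 0.112. In this contrast 0 genes passed when adjusted over the list alone, and 8 did without irradiated mutant replicate 1 and 3 without irradiated mutant replicate 2. Cdkn2a, which encodes the senescence marker p16, was at 2.22 ± 1.10 CPM in irradiated wild type and 7.53 ± 0.0774 in irradiated mutants (adjusted p = 1.0). Cdkn1a was at 49.4 ± 0.294 and 110.1 ± 67.3 CPM. Between irradiated and unirradiated mutants the list had a median of 1.59 (adjusted p = 0.0342, or adjusted p = 0.920 with an estimated correlation). The call was lost without unirradiated mutant replicate 1 (adjusted p = 0.136) and irradiated mutant replicate 2 (0.762). Over all genes Cdkn1a rose and Mmp9 fell, and adjusted over the list alone 7 of the 28 senescence and secretory genes rose and 4 fell. Without unirradiated mutant replicate 1 or 2, 1 rose and 1 fell over the list alone, and without unirradiated wild type replicate 1 or 2, 5 rose and 2 fell. Without irradiated mutant replicate 1, 15 rose and 4 fell, and without irradiated mutant replicate 2, 5 rose and 6 fell. Timp1, an inhibitor of matrix metalloproteinases, was at 2.96 ± 0.358 and 19 ± 12.3 CPM.

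In wild type, 4 of the 28 senescence and secretory genes rose after irradiation and 2 fell when adjusted over the list alone (list median 0.75; adjusted p = 0.117). Without unirradiated wild type replicate 1 or 2, 0 passed over the list alone. The nuclear lamina and envelope list passed in none of the 5 contrasts (adjusted p from 0.0908 to 0.764). Zmpste24, the protease that processes prelamin A, was at 43.9 ± 5.95 CPM in unirradiated wild type and 71.9 ± 0.998 in unirradiated mutants (adjusted p = 1.0). The DNA repair, dendritic cell, stem and progenitor, NF-kB and inflammatory, heterochromatin, apoptosis and unfolded protein response lists did not pass between unirradiated genotypes, with medians from -0.16 to 0.30.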

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

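The interaction tests of the lists were planned, and the tests that weigh explanations for the granulocyte and macrophage genes were chosen after those results had been seen. Camera with the preset correlation found 11 lists whose change from unirradiated to irradiated libraries differed between genotypes. With an estimated correlation 0 lists passed (adjusted p from 0.528 to 0.877). In both genotypes irradiation, day and sex-linked transcripts changed together. The interaction therefore cannot separate a dependence on irradiation from one on sex, day or library preparation. The median interaction, as the log2 response in mutants less that in wild type, was -1.36 for the granulocyte list and 0.84 for the macrophage and monocyte list, and these 2 kept their call and direction whichever library was left out. The other 9 lost it without at least 1 library. They were adipose (4.18), stroma and matrix (1.42), endothelial (0.35), p53 targets (0.27), interferon-stimulated (-0.36), DNA repair (-0.36), cell cycle (-0.41), plasma cell (-0.49) and dendritic cell (-0.53) genes. The cell cycle list turned to 0.25 without irradiated mutant replicate 2 (adjusted p = 0.0122).

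Granulocyte genes were higher in unirradiated mutants (median 2.40). More blood left in the mutant spleens should raise genes of mature neutrophils and leave those of precursors, which stay in blood-forming tissue. The primary granule genes Mpo, Elane, Prtn3 and Ctsg, made by precursors, had a median of 2.40 (SD 0.21), which argues against mature blood neutrophils alone. The other 16 granulocyte genes had a median of 2.41. They include genes of precursors such as Fcnb, so they do not stand for mature neutrophils. Blood that carried precursors could not be told apart by these genes. A lower share of lymphocytes should raise every other cell type alike, but the highest median among the other non-lymphoid lists was 0.25, against 2.40 for granulocyte genes (SD 0.44 over these genes), which argues against dilution. More production of granulocytes in mutant spleens may account for the pattern, as a hypothesis that was not tested, and differences in infection or housing between these mice were not tested either.

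Macrophage genes were higher in irradiated mutants (median 1.13, SD 1.05). Liver or adipose tissue in the samples should raise them most in the library that holds most of it. The 2 irradiated mutant libraries differed by 2.27 in mean log2 CPM of hepatocyte genes and by 3.74 in that of adipose genes. They differed by 0.08 in that of the macrophage and monocyte list, which argues against either tissue alone for the list mean. Their erythroid list means also differed (10.63 and 7.08 log2 CPM), so like macrophage means need not mean like macrophage content. Single members of the macrophage and monocyte list, such as Cd5l and Vsig4, differed widely between these libraries, and for them neither tissue is argued against. A lower share of the main cell types could not be excluded, because the lowest median of the other non-lymphoid lists was -0.030 and members of the list spread by 1.05, so it and a change in macrophages cannot be told apart for these genes. Liver in 1 library together with adipose tissue in the other, or a larger or more active macrophage population in irradiated mutants, may also account for the pattern, and neither was tested.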

How the results depend on the processing

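Of the alternatives, limma-voom with library weights, robust empirical Bayes, X and Y genes left out and list tests on only the groups compared were chosen after seeing the data, and the others were planned. Counts of genes are given for the genotype effect without irradiation, the genotype effect after it, irradiation in wild type, irradiation in mutants, the interaction, and calls shared between genotype and between irradiation contrasts, which were 0, 0, 10, 104, 0, 0 and 10. RLE scaling, the stricter filter, robust empirical Bayes and the 2-fold threshold kept all of them within 1.5 times. Without a low-count filter they were 143, 168, 1580, 2147, 52, 42 and 1061, and with DESeq2 55, 61, 917, 1710, 2, 5 and 630. Without scaling factors irradiation in mutants gave 60 and shared irradiation calls 6. Irradiation in wild type and shared irradiation calls gave 5 and 5 with limma-voom, 598 and 77 with library weights, 0 and 0 without X and Y genes, and 4 and 4 at an adjusted p under 0.01, where mutants gave 5. With library weights the genotype effect without irradiation gave 395. Fits on only the groups compared gave 469 for the genotype effect without irradiation, 1107 for irradiation in wild type, 0 in mutants and 0 shared. The cause was not tested, except that the fit on the unirradiated libraries leaves the irradiated replicates out of the spread by construction.

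Leaving out 1 library gave 0 to 15, 0 to 482, 0 to 2551, 3 to 4428, 0 to 0, 0 to 5 and 0 to 1988 genes in the same order, where a lone sample is assumed to vary like the other groups. Lists past the threshold were 11, 17, 11, 13 and 11 in the 5 contrasts, 1, 0, 1, 0 and 0 with an estimated correlation, 0, 0, 4, 4 and 0 with fry (for irradiation, the 11, 13, 4 and 4 hold the sex-linked list, which was also the 1 list with an estimated correlation in wild type), and 7 to 12, 7 to 18, 9 to 15, 13 to 17 and 7 to 18 with 1 library left out. Some lists turned with 1 library left out. Between irradiated genotypes these were the cell cycle (0.55, adjusted p = 4.72e-06) and erythroid (0.90, adjusted p = 4.16e-14) lists without irradiated mutant replicate 2 and the T cell list (0.82, adjusted p = 5.04e-07) without irradiated mutant replicate 1. Adjusted p over the fits that left out 1 library ran from 2.48e-22 to 0.299, from 2.35e-48 to 0.694 and from 1.94e-37 to 0.739 for these lists. For irradiation in mutants the erythroid list turned (-0.87, adjusted p = 3.90e-06) without irradiated mutant replicate 1, with a range from 1.93e-30 to 0.0111. For the interaction the cell cycle list turned (0.25, adjusted p = 0.0122) without irradiated mutant replicate 2, with a range from 4.76e-28 to 0.789. Of values for named genes, 5733 kept side and direction, 433 passed newly, 238 no longer passed, 26 moved and 0 turned. Of values for lists, 1697 kept them, 83 passed newly and 214 no longer passed.

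With the replicate number as a replicate block, 16 genes were called for irradiation in wild type, 253 in mutants (136 higher, 117 lower) and 16 in both. Replicate differences correlated by 0.0349 to 0.465 across genes between groups, over 0.1 in 4 of the 6 pairs of groups. No label says that the numbers pair mice, and whether same-numbered samples had a litter or day in common stays open. The depth of 12100784 to 19455470 counts limits what can be said of genes near the floor of 3 counts.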

Other observations

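The tests of sex and batch given here were chosen after the result was seen, and the other values were not part of a planned comparison. Immunoglobulin variable segments, the parts of antibody genes that bind antigen, were a group chosen after their values had been seen, and were not tested as a set. Of 183 segments tested, 171 lay above 0 between unirradiated genotypes (median log2 fold change 1.48). At an unadjusted p under 0.05, 74 were higher and 0 lower in mutants. Of these 183 segments, 156 also lay above 0 between irradiated genotypes (median 1.71), where 68 were higher and 3 lower at an unadjusted p under 0.05. In the fit on the unirradiated libraries alone, 90 of 194 variable segments were called higher and 1 lower, which made up 90 of the 378 genes called higher. In the fit on the wild-type libraries alone, 82 of 158 were called lower after irradiation and 0 higher. Reads of near-identical segments may be exchanged between them, and with globin, immunoglobulin and T cell receptor genes left out edgeR called 0 genes between genotypes in either condition, with 316 and 625 at an unadjusted p under 0.05.

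Transcripts of liver were present in irradiated libraries, and those of adipose tissue in libraries of both conditions. Of 19 hepatocyte genes, 1 reached 1 CPM on average in unirradiated libraries, and 0 stood in another list. Their mean was 0.70 and 0.75 log2 CPM in irradiated wild type and 3.21 and 0.94 in irradiated mutants. Alb, the most abundant liver transcript, had 698 and 799 counts in irradiated wild type and 2674 and 698 in irradiated mutants. Apoa1, an apolipoprotein made by liver, had 80, 82, 454 and 68 counts in these libraries and 0, 0, 1 and 1 in unirradiated wild type and mutants. Rmrp, an RNA without a poly(A) tail, had 7 and 3 counts in irradiated wild type and 22 and 0 in irradiated mutants, against at most 1 in unirradiated libraries. Adipose means were higher in replicate 2 than in replicate 1 of every group. In log2 CPM they were -0.35 and 2.68 in unirradiated wild type and -0.70 and 1.74 in unirradiated mutants. In irradiated wild type they were -0.76 and 2.94, and in irradiated mutants 2.24 and 5.97. Globin genes took 10.3% and 1.30% of counts in the 2 irradiated mutant libraries.

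The sex-linked and the autosomal calls between irradiated and unirradiated libraries were weighed against sex. Irradiated libraries had a highest sum of 0 counts over the Y-linked genes, against a lowest sum of 4318 in unirradiated ones, so the sex-linked calls go with female irradiated and male unirradiated mice. For the 98 autosomal genes among the 104 called in mutants, sex, day and irradiation cannot be told apart, since no irradiated library carried Y-linked transcripts. A difference in library preparation between the days is likewise open, because all 4 irradiated and 0 unirradiated libraries had over 3 counts of Alb. Rpph1 and Rn7sk, RNAs without a poly(A) tail, had more counts in each of these 4 libraries than in any unirradiated one. The same held for the ribosomal sequence CT010467.1, at 6300 to 29151 CPM in irradiated and 438 to 931 CPM in unirradiated libraries. Irradiation, sex and preparation may each account for part of the autosomal calls.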
